A study of Homo sapiens with 12 samples.

How the data were processed

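The RNA libraries were quantified by the authors with kallisto against hg38, per the submitters' processing notes, which state no versions. The values used are the deposited CPM values (reads per 1000000), which the authors made from the kallisto transcript estimates of each library, and every column sums to 1000000. The same table carries, for each comparison, a column of log2 ratios that the authors computed from mean CPM, a p-value column with the authors' adjusted p-values, and a score that is the −log10 of the adjusted p as deposited. These result columns were used only as a check. No column of per-sample values was left unused. The MeRIP-seq data that the series describes were not analysed here.

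Depth was read from the smallest step of each CPM column, which implies 38.5 to 48.2 × 10⁶ reads a library (median 40.7). The estimates are fractional, since kallisto divides reads among transcripts. Only 11.1 to 12.7% of transcript values and 47.1 to 56.5% of gene sums came out whole within 0.01 of a read. No whole counts could be recovered, so the test planned for counts was not run, and the fallback for normalised values, which had been set out before the data were examined, took its place. Sampling precision could therefore not be given as a count interval, and errors are SDs over libraries and standard errors from the model.

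Of 110474 transcripts 103739 carried a gene name in the file, 6195 were named through GENCODE v29, whose build of GRCh38 may differ from the authors' annotation, and 540 had no gene name (0.15 to 0.19% of CPM). Transcripts were summed to 19663 genes. The 13168 genes with at least 1 CPM in at least 3 libraries were tested. No library was left out. Grouping followed the labels, with 3 libraries in each of 4 groups. Pairs of libraries of the same group differed well beyond sampling noise, so none was taken as the same library given more than once.

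The test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(CPM + 1), with all 12 libraries in a single model of 4 groups (8 residual degrees of freedom, prior 4.84). Each adjusted p for a gene is a moderated t-test adjusted by Benjamini and Hochberg over all genes tested, with 0.05 as the threshold. Error bars and ± values are SDs, and SE is the moderated standard error. The difference between the knockout and overexpression responses was a contrast of the same model. Lists of genes, 33 in number with 613 of 721 genes measured, were written before the data were examined and tested with camera at a preset correlation of 0.01. Their 66 tests in the main comparisons were adjusted together. The preset correlation is generous when genes of a list vary together, so the p with an estimated correlation is given beside it. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. On tables simulated with the measured spread and known changes, 2-fold changes were recovered for 73.1% of genes in the knockout comparison and 86.6% in the overexpression comparison. For 1.5-fold changes the shares were 35.8% and 40.3%. The changed genes (67 for each of these folds) were drawn at random from those with a mean of at least 5 CPM. Both comparisons used the same spread, so the gap between them does not show a difference in power. Simulated genes varied independently, whereas 57.0% of the real within-group variance lay on 1 component. The shares therefore do not give the sensitivity over all genes tested.

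Genes are named by a rule set before the data were examined. It takes the m6A writer complex, the 10 largest rises and the 10 largest falls of each comparison and up to 4 members of each list. The largest changes were taken among genes past the test with groups that did not overlap, a higher group mean of at least 5 CPM and an ordinary symbol, and list members by the smallest p. Genes with opposite changes were taken by the larger of the smaller effects. Some genes that the rule names are not reported here. OAS1, MX1, CLDN1, KRT6A and KRT16 and the genes compared across all 4 groups were chosen after their values were seen.

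Replicate numbers might mark shared preparation, so residuals of same-numbered libraries were correlated, with a limit of 0.1. The predictions that use this limit were written after the data had been seen. The correlations were 0.25, 0.59 and 0.37 for empty vector and knockout. By the limit the numbers paired the knockout comparison and no comparison with dCas9, so blocked values stand beside knockout results where they change a call or a count by more than 1.5 times. The blocked counts were already known when the correlations were read, so this choice was not independent of them. The alternatives fixed before the data were examined were no filter on level, pseudocounts of 0.1 and 10, the replicate block, a minimum log2 fold change of 1, fits of 6 libraries alone, single libraries left out, and other tests of lists. Added after the data had been seen were scaling by median ratios, a correction of each library for gene GC content (lowess with a span of 0.3, 13145 genes with a GC value), that correction with the block, a batch term for the side of component 1, a fit without the 3 AT-rich libraries outside dCas9, the exchange of controls and the chromosome test. The chromosome test took the 9948 genes with a mean log2 level of at least 3.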

Results

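The series measured RNA by sequencing in BPH1, an established line of immortalised prostate epithelial cells. ZC3H13, the gene manipulated, encodes a zinc finger protein of the nuclear complex that writes N6-methyladenosine (m6A) onto messenger RNA. The 12 libraries fall into 4 groups of 3: cells with ZC3H13 knocked out, their empty vector control, cells that overexpress ZC3H13 through a dCas9-based activator, and their dCas9 control. All were grown with 20% fetal bovine serum and 20 ng/ml dihydrotestosterone. The deposited table gives CPM values for each library, reads of a transcript per 1000000, rather than counts. The most frequent non-zero value of a library is 0.0208 to 0.026 CPM. Taken as 1 read, it implies 38.5 to 48.2 × 10⁶ reads a library. After transcripts were summed per gene, 13168 genes were tested, and each mean below is given in CPM with its SD over 3 libraries. Genome positions are those of GRCh38.

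The libraries differed most along a component that held 46.0% of the variance and followed the GC content of genes. All 3 dCas9 libraries lay on its AT-rich side (scores −31.9 to −12.5), together with replicate 2 of each other group, and the remaining 6 libraries lay on its GC-rich side. On component 2, with 18.4% of the variance, the empty vector libraries scored 19.8 to 23.9, the overexpressing libraries 1.9 to 4.9, the dCas9 libraries −9.4 to −7.5 and the knockout libraries −18.5 to −10.0.

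**Figure D1:**
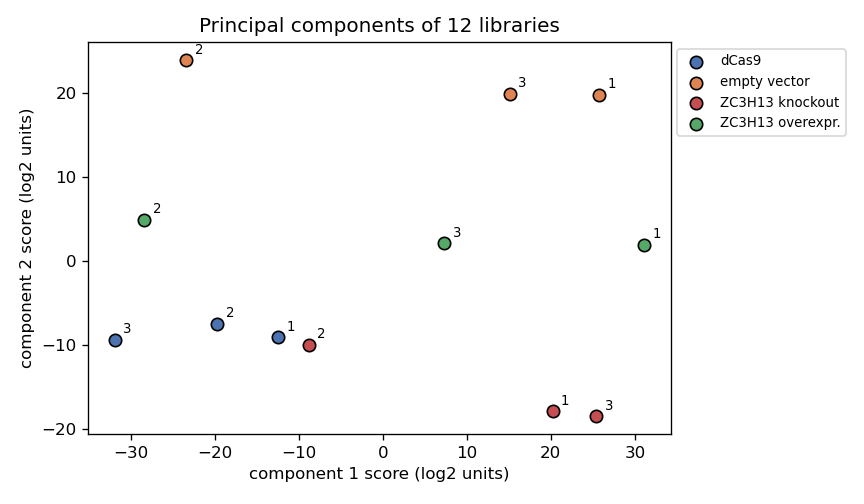
Scores of the 12 libraries on principal components 1 (x axis) and 2 (y axis) of the log2 values, in log2 units, coloured by group and numbered by replicate. The 3 empty vector libraries sit at 19.8 to 23.9 on component 2, above the other 9, while each group but dCas9 spreads over both sides of component 1.

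The first question is how far the level of ZC3H13 RNA itself moved. ZC3H13 (ENSG00000123200, protein coding, minus strand of chromosome 13, 45954465 to 46052759) stood at 42.1 ± 2.32 CPM in knockout cells and 51.0 ± 11 CPM in empty vector cells. This difference of −0.25 on the log2 scale (SE 0.20) did not pass the test (limma adjusted p = 0.59). In overexpressing cells ZC3H13 stood at 110.2 ± 36.4 CPM against 53.5 ± 5.11 CPM in dCas9 cells, a 2.06-fold ratio, and each overexpressing library (81.2, 151.0 and 98.3 CPM) lay above every dCas9 library (49.6 to 59.3 CPM). Its log2 fold change of 0.98 (SE 0.20) missed the threshold (adjusted p = 0.073). It passed without overexpression replicate 2 (log2 fold change 0.73, adjusted p = 0.049) and after a GC correction (1.22, adjusted p = 5.9e-05), and its adjusted p ranged from 2.3e-05 to 0.25 over all settings. The response of ZC3H13 itself differed between the comparisons, by −1.23 (interaction adjusted p = 0.026). None of the other 7 members of the writer complex that were measured (METTL3, METTL14, WTAP, VIRMA, RBM15, RBM15B and CBLL1) passed in either comparison, and the list as a whole gave adjusted p = 0.33 for knockout and 0.99 for overexpression (camera). METTL3, the catalytic subunit, stood at 43.6 to 51.5 CPM in the 4 groups. RNA level alone does not show whether the protein was lost, since an edited gene can still be transcribed.

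**Figure D2:**
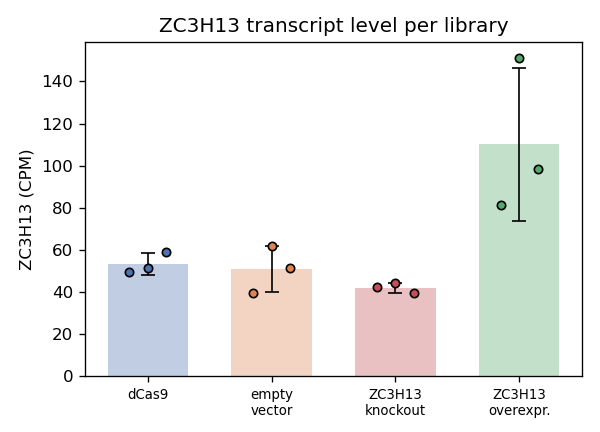
ZC3H13 level (y axis, CPM) in the 4 groups (x axis), with each library as a point, the mean of 3 libraries as a bar and the SD as an error bar. The overexpressing libraries lie at 81.2 to 151.0 CPM, above all others, and the knockout libraries at 39.6 to 44.2 CPM, overlapping the empty vector libraries (39.7 to 61.7 CPM).

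The knockout was compared with the empty vector control to ask which transcripts differ in the cells labelled as ZC3H13 knockout, whose ZC3H13 RNA was not measurably lower. Genes of the interferon response and of MHC class I antigen presentation were lower in knockout cells, while genes of the extracellular matrix, of the mesenchymal state and of cholesterol synthesis were higher. As lists they passed only with the preset correlation, with adjusted p = 0.077, 0.18, 0.32, 0.077 and 0.18 in this order with an estimated correlation. In all, 650 of 13168 genes changed (4.94%), 357 up and 293 down, of which 177 differed at least 2-fold. For the genes named as largest changes, all 3 libraries of one group lay above all 3 of the other. Among all genes tested, 21.7% parted the groups in this way, against 10% by chance.

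The largest rise belonged to CBLN1 (ENSG00000102924, chromosome 16, 49277917 to 49281831), a secreted organiser of synapses, at 38.8 ± 7.13 CPM in knockout and 5.55 ± 0.819 CPM in empty vector cells (log2 fold change 2.60, SE 0.17, adjusted p = 1.4e-05). EDN2, which encodes the vasoactive peptide endothelin 2, rose by 2.40, the transcriptional coregulator MN1 by 2.39 and PSTPIP1 by 1.94. KCNMA1, a calcium-activated potassium channel, rose by 1.89, as did CREB3L1, a membrane-bound transcription factor. LCP1, which bundles actin filaments and lies near ZC3H13 on chromosome 13, rose by 1.84. The proteases ADAMTS15 and MMP13 rose by 1.83 and 1.80. CGB8 rose by 1.86, but it belongs to a cluster of near-identical genes whose reads cannot be assigned with certainty. The largest falls were those of S100A8 and KRT4 (each by 2.22). S100A8 and S100A9, which fell by 2.13, encode the subunits of the antimicrobial protein calprotectin. KRT4 and SPRR3, genes of stratified epithelia, fell from 114 ± 7.49 to 24.4 ± 6.75 CPM and from 23.9 ± 2.52 to 5.26 ± 0.251 CPM. PI3, an elastase inhibitor of epithelia, fell by 1.90, the deubiquitinase UCHL1 by 1.98, the adaptor GRB10 by 2.10 and the coactivator EYA4 by 1.92. The adjusted p of the 20 largest changes, which also include OASL and RSAD2, ranged from 1.4e-05 to 0.023. Against dCas9, the other control labelled wild type, 0 genes passed in the same fit. CBLN1 and KRT4 in the knockout (32.9 to 46.7 and 16.7 to 29.1 CPM) lay near dCas9 (46.6 to 59.8 and 17.6 to 34.7 CPM). Others, such as CREB3L1, stayed higher in the knockout (6.7 to 12.6 against 3.1 to 5.0 CPM). The changes named here therefore cannot be laid to the knockout rather than to the empty vector cells.

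Of 35 measured genes of the type I interferon response, 15 fell and none rose (26 fell when adjusted over the list alone, and 26 with the replicate block), with a median log2 fold change of −0.90. OASL fell from 73.8 ± 14.5 to 17.6 ± 4.74 CPM, RSAD2 from 19.3 ± 8.19 to 3.87 ± 0.583 CPM, HERC5 by 1.87 and MX1 by 1.23. The list passed the set test (camera adjusted p = 8.2e-20), and gave adjusted p = 0.077 with an estimated correlation. Among 15 genes of MHC class I presentation 7 fell (9 adjusted over the list alone), including HLA-B (from 631 ± 70.1 to 291 ± 14.0 CPM), HLA-F and the peptide transporter TAP2 (camera adjusted p = 6.1e-08, and 0.18 with an estimated correlation). Reads of HLA genes are shared between paralogs and depend on alleles, so single HLA values are uncertain. In the 2 control groups these genes also differed. Of the interferon genes 6 were higher in empty vector than in dCas9 cells and none lower, and so were 6 of the MHC class I genes. HLA-B stood at 265 ± 42.1 CPM in dCas9 cells and ISG15 at 137 ± 8.49 CPM, against 256 ± 23.9 CPM in empty vector and 111 ± 14.8 CPM in knockout cells.

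Matrix and mesenchymal genes rose. Among 25 collagen and matrix genes 9 rose (14 up and 1 down adjusted over the list alone), with COL1A1 at 71.4 ± 22.7 against 21.3 ± 2.73 CPM, COL7A1 up by 0.96 and FN1, encoding fibronectin, up by 0.78 (camera adjusted p = 1.8e-08, and 0.32 with an estimated correlation). Of 17 mesenchymal genes 6 rose (8 adjusted over the list alone), among them TNC (tenascin C, 1.33), TAGLN (1.33), SPARC (0.93) and VIM (0.91), at 404 ± 23.9 against 211 ± 6.33 CPM for SPARC (adjusted p = 5.7e-06, and 0.077 with an estimated correlation). Of 24 matrix proteases and inhibitors 7 rose and 3 fell (10 and 3 adjusted over the list alone), with MMP2 up by 1.04, MMP9 by 1.02 and MMP14 by 0.67 (adjusted p = 0.0069, and 0.11 with an estimated correlation). The TGF-beta target list had 5 rises and 1 fall among 23 genes (9 and 2 adjusted over the list alone, 8 and 3 with the replicate block), including TGFBI (0.63), TGFB2 (1.00) and INHBA (1.15), at adjusted p = 7.1e-04, and 0.26 with an estimated correlation. The lists overlap in some of their genes, such as TNC and FN1. The mesenchymal list was lower in empty vector than in dCas9 cells (adjusted p = 0.0041, and 0.29 with an estimated correlation), with SPARC, TNC and CDH2 among the genes past the test there.

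Further lists also passed. Of 24 cholesterol synthesis genes and targets of the transcription factor SREBP2, 6 rose (10 adjusted over the list alone, 11 with the replicate block). Among them were NSDHL, SQLE and MSMO1 (0.66 each). The list gave camera adjusted p = 7.5e-08, and 0.18 with an estimated correlation. Among 12 prostate basal markers the keratins KRT5 (0.92), KRT14 (0.43) and KRT17 (0.43) rose and the adhesion receptor CD44 fell by 0.52 (6 and 1 both when adjusted over the list alone and with the replicate block; adjusted p = 0.014, and 0.20 with an estimated correlation). The unfolded protein and ATF4 list shifted upward with 1 of 29 genes past the test, the pseudokinase TRIB3 (0.53), none adjusted over the list alone and 3 with the replicate block (adjusted p = 5e-04, and 0.077 with an estimated correlation). Of 28 immediate early and MAPK feedback genes 3 fell (5 adjusted over the list alone, 8 with the replicate block), namely the ERK phosphatase DUSP6 (by 1.36) and the EGF receptor ligands EREG (by 1.60) and AREG (by 1.14), at adjusted p = 0.002, and 0.60 with an estimated correlation. Among 47 cytosolic ribosomal protein genes RPS13 and RPS14 fell, also when adjusted over the list alone, and 4 fell with the replicate block (adjusted p = 0.034, and 0.87 with an estimated correlation). No knockout list therefore passed with an estimated correlation, while a rotation test of each list by itself (fry) passed 13 lists, 9 of these 11 among them.

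Several lists did not pass as a whole but held changed genes. Of 22 measured genes associated with metastasis 4 rose, including the collagen crosslinker LOXL2 (1.04) and the scaffold NEDD9 (1.09), and 5 fell, including S100P (by 1.25) and CD44 (camera adjusted p = 0.82). Among hypoxia genes NDRG1 (1.38), EGLN3 (0.86) and DDIT4 (0.45) rose (adjusted p = 0.056, and 0.049 with the replicate block). Of the Wnt genes DKK3 rose by 0.57, and SFRP1 and CCND1 fell by 1.64 and 0.39 (adjusted p = 1). Of 34 cell cycle genes the replication factor MCM3 fell, by 0.39 (adjusted p = 0.26), and with the replicate block 4 fell and 1 rose. Of 3 measured fibroblast markers COL1A1 rose by 1.65 (median 0.72, camera adjusted p = 0.074, and 0.0041 by fry), while COL1A2 and FAP did not pass. Of 3 measured immune cell markers 1 rose (camera adjusted p = 0.78). It was CSF1R, at 2.1 to 2.8 CPM in knockout and 0.22 to 0.70 CPM in empty vector libraries. Of the same 3 markers 1 was lower in empty vector than in dCas9 cells. None of 24 epithelial adhesion genes and none of 14 m6A readers and erasers changed (adjusted p = 1 and 0.33), though the tight junction gene CLDN1 of the first list passed with the replicate block (adjusted p = 0.034). In all, 21 of the 33 lists passed in neither of the main comparisons.

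The count of changed genes depended on the model. With the replicate number as a block, which the correlation check allowed for this pair of groups, 1453 genes passed, after a GC correction 1705, and in a fit of these 6 libraries alone 253. It also depended on single libraries, with 417, 346 and 272 genes without empty vector replicate 1, 2 or 3, and 223 and 230 without knockout replicate 1 or 3, though no gene of the 650 changed sign.

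**Figure D3:**
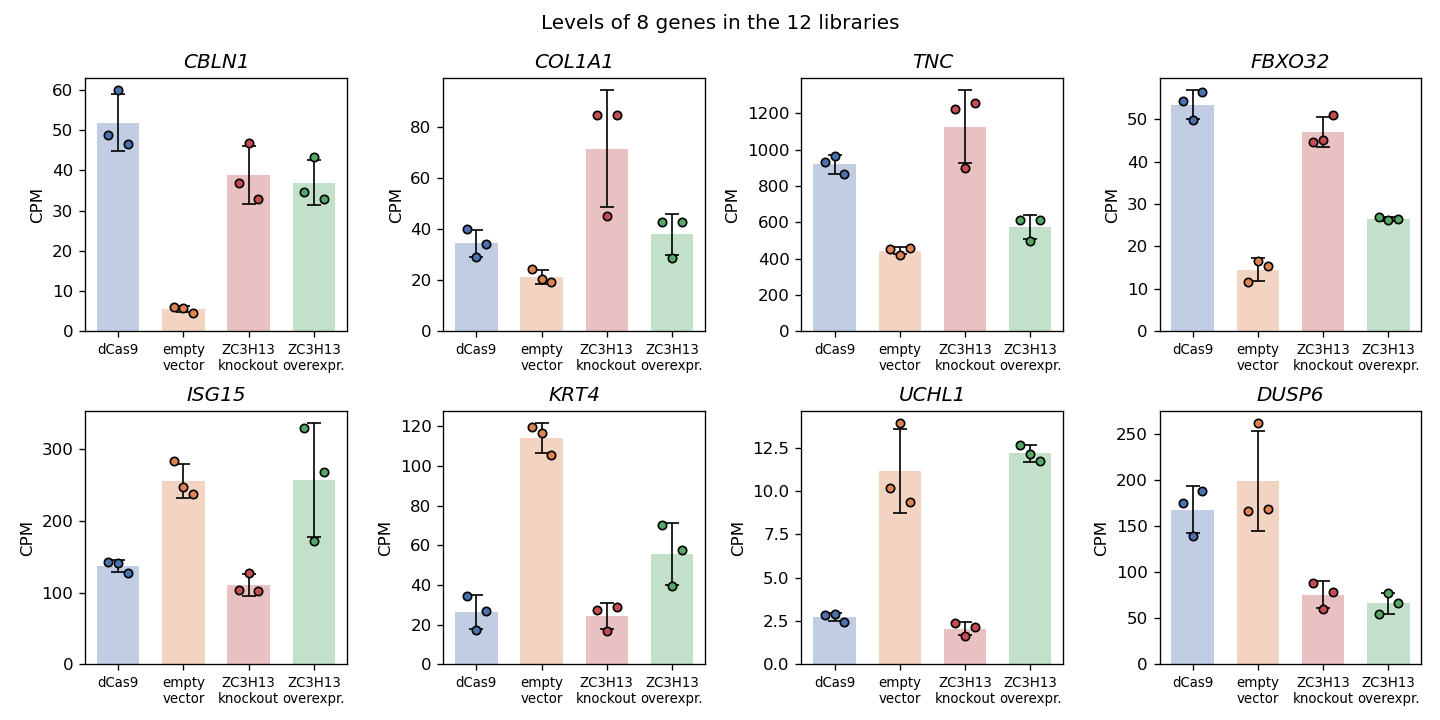
Levels of 8 genes (y axes, CPM) in the 4 groups (x axes), with each library as a point, the mean of 3 libraries as a bar and the SD as an error bar. For CBLN1, FBXO32, KRT4 and UCHL1 the knockout means (38.8, 46.9, 24.4 and 2.07 CPM) lie nearer to dCas9 (51.8, 53.4, 26.4 and 2.74 CPM) than to empty vector (5.55, 14.5, 114 and 11.1 CPM), while DUSP6 is lower in both manipulated groups (75.9 and 66.2 CPM) than in both controls (168 and 199 CPM).

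The controls, both labelled wild type, were compared with each other to see how far the backgrounds of the main comparisons differ. They differed in 635 genes (4.82%), 312 higher and 323 lower in empty vector cells. CBLN1 was lower in empty vector cells by 3.01 on the log2 scale, FBXO32, a ubiquitin ligase subunit, by 1.82, and LCP1 by 1.84, whereas KRT4 was higher by 2.12, the stathmin STMN3 by 1.79 and UCHL1 by 1.68. Of the 650 genes that differed between knockout and empty vector, 344 (52.9%) also differed between the controls, each in the opposite direction, so that the empty vector libraries were the ones apart. For lists without any shared library 15.7 would be expected. Sharing the empty vector libraries favours such a mirror. Unchanged groups simulated with the same sharing gave at most 1 gene in 20 runs, but few genes can pass at all in such groups. The runs therefore cannot tell how far sharing built the overlap of 344. Across all genes the log2 fold changes of these comparisons gave Pearson's r = −0.57, against −0.5 in unchanged simulated groups. ZC3H13 was not among these genes (−0.08 between controls, adjusted p = 0.82).

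Set against dCas9 in place of the empty vector, the knockout had 0 genes past the limma test in the fit of all 12 libraries, with 1988 at an unadjusted p under 0.05. In a fit of these 6 libraries alone 355 passed, of which 337 were lower. After the GC correction 0 passed, and 19 did with the replicate block added. Adjusted over the list alone, 13 of 35 interferon genes and 5 immediate early genes were lower, and 4 mesenchymal and 3 matrix genes higher. As sets, the collagen and matrix list stayed higher in the knockout (median 0.28, camera adjusted p = 9.7e-07) and the interferon list lower (median −0.36, adjusted p = 9.7e-07), with adjusted p = 0.59 and 0.29 with an estimated correlation. The mitochondrially encoded list was higher (adjusted p = 8.1e-06, and 0.61 with an estimated correlation) and the cell cycle list lower (0.019, and 0.68 with an estimated correlation), though neither passed against empty vector. In all 9 lists passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.29), whereas the MHC class I, protease, TGF-beta, unfolded protein and ribosomal lists did not (adjusted p = 0.49, 0.37, 0.15, 0.68 and 0.47). DUSP6 stood at −1.14 and COL1A1 at 0.99 in this comparison without passing. The count between the controls was 298, 299 and 161 without dCas9 replicate 1, 2 or 3, and 213, 1146 and 199 without empty vector replicate 1, 2 or 3. After the GC correction it was 1526, and with the side of component 1 as a batch term 1253.

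Whole chromosomes differed between the controls as well, in a test chosen after the data had been seen. After GC correction, the 102 tested genes of chromosome 21 had a median log2 fold change of −0.34 in empty vector against dCas9 cells, and those of chromosomes 11, 6, 5 and 17 medians of 0.20, 0.18, 0.16 and 0.16. With an estimated correlation 15 of 23 chromosomes passed the set test for empty vector against dCas9, 13 for knockout against empty vector, 11 for overexpression against dCas9, and 0 for knockout against dCas9 (1 with the preset correlation). In the knockout against dCas9 all 23 medians lay between −0.06 and 0.05. Of the genes tested on chromosome 21, 15.7% changed between knockout and empty vector, 18 up and 2 down.

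**Figure D4:**
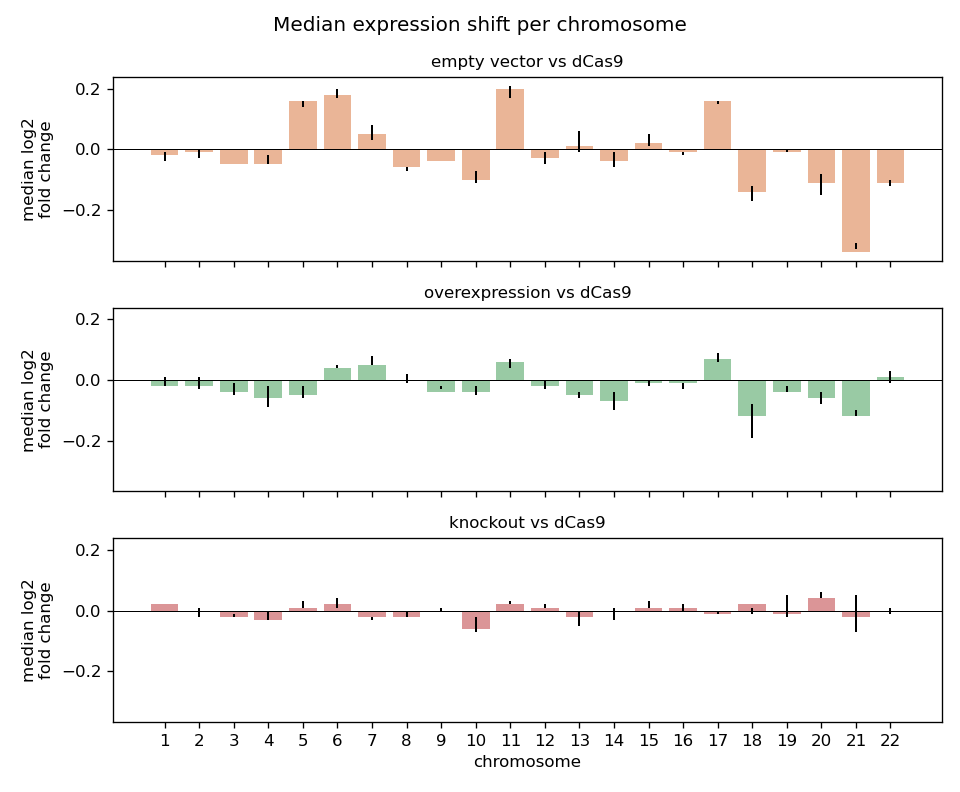
Median GC-corrected log2 fold change (y axes) of the genes on each of the 22 autosomes (x axis) for empty vector, overexpression and knockout, each against dCas9; bars are medians of the group fold changes and lines span the medians of the 3 single libraries. Empty vector cells range from −0.34 on chromosome 21 to 0.20 on chromosome 11, and knockout cells stay within −0.06 and 0.05.

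Overexpression was compared with dCas9 to ask which transcripts differ in the cells labelled as overexpressing ZC3H13. Few genes changed, 18 up and 6 down (0.182% of 13168), and 15 of these 24 differed at least 2-fold. ALPP (ENSG00000163283, chromosome 2, 232378534 to 232382889), encoding placental alkaline phosphatase, rose most, to 89.5 ± 21.4 from 13.3 ± 7.25 CPM (log2 fold change 2.75, SE 0.31, adjusted p = 0.003), although its close paralogs make the assignment of its reads uncertain. UCHL1 rose by 1.82, the germline and leukaemia-associated cyclin CCNA1 by 1.59, the matrix protein THBS2 by 1.42 and NEURL1 by 1.32. STMN3 rose by 1.08, the membrane skeleton protein ADD2 by 1.07, CPNE7 by 1.03 and SLC16A3, which exports lactate, from 132 to 273 CPM. Among the falls were those of EDN1 (endothelin 1, from 38.4 ± 13 to 10.4 ± 2.49 CPM), the ferroxidase HEPHL1 (by 1.45), DUSP6 (by 1.33), FBXO32 (by 0.98) and CDH2, encoding N-cadherin (by 0.59). Of all genes tested, 16.1% had groups that did not overlap, against 10% by chance.

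As sets, interferon genes were higher in overexpressing cells (35 measured, none past the test alone, 13 adjusted over the list alone, median 0.45; camera adjusted p = 4.8e-10, and 0.11 with an estimated correlation). ISG15 stood at 256 ± 79.1 against 137 ± 8.49 CPM and OAS1 at 48.9 ± 20.2 against 17.8 ± 0.263 CPM. MHC class I genes were higher with none of 15 past the test and 4 adjusted over the list alone (adjusted p = 1.7e-04, and 0.32 with an estimated correlation). The mesenchymal list was lower, with 2 of 17 genes past the test, CDH2 among them, and 8 adjusted over the list alone (adjusted p = 6.8e-06, and 0.077 with an estimated correlation). Of 28 immediate early and MAPK feedback genes DUSP6 fell, and 6 did when adjusted over the list alone (adjusted p = 3.8e-05, and 0.51 with an estimated correlation). The 13 mitochondrially encoded genes were higher as a set with none past the test in either count (adjusted p = 0.016, and 0.74 with an estimated correlation). The interferon, MHC class I and mitochondrial lists were also higher, and the mesenchymal list lower, in empty vector than in dCas9 cells, with adjusted p = 0.29, 0.29, 0.68 and 0.29 with an estimated correlation.

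The count of 24 was 8 and 4 without dCas9 replicate 1 or 3, 9, 207 and 6 without overexpression replicate 1, 2 or 3, 7 in a fit of these 6 libraries alone, and 128 after the GC correction. CDH2 lost its call after that correction, at −0.44 with adjusted p = 0.058.

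Genes called in both comparisons were examined to see whether the groups labelled knockout and overexpression moved genes in opposite directions. Of the 24 genes changed on overexpression 16 also changed in the knockout in the opposite direction, among them UCHL1, NEURL1, STMN3, LAMA1, ADD2 and CPNE7 (up on overexpression, down in knockout) and EDN1, HEPHL1 and FBXO32 (down on overexpression, up in knockout). Independent lists would share 0.401 genes of the first kind, where 12 were found (Fisher's exact test, 2-sided, p = 1.9e-16), and 0.163 of the second, where 4 were found (p = 7.6e-06). These p-values treat genes as independent, although genes vary together and both lists come from the same fit. They do not measure the spread over libraries. Of the 16 genes 14 also differed between the controls, all of them with empty vector on the side of overexpression. UCHL1, for example, stood at 12.2 ± 0.477 CPM in overexpressing, 11.1 ± 2.42 in empty vector, 2.74 ± 0.234 in dCas9 and 2.07 ± 0.393 CPM in knockout cells. In the direction of the knockout, the median difference of the 16 genes was 1.23 against empty vector and 0.04 (−0.37 to 0.59) against dCas9. Across all genes, which are not independent replicates, the log2 fold changes of the main comparisons gave Pearson's r = −0.15 and Spearman's rho = −0.04, and r = −0.33 after the GC correction. Only 3 genes changed in the same direction in both comparisons. KRT6A and KRT16, keratins of activated epithelium, rose in both (0.90 and 1.01 in the knockout, 0.68 and 0.94 on overexpression), and DUSP6 fell in both, at 75.9 ± 14.7 CPM in knockout and 66.2 ± 11 CPM in overexpressing cells, against 199 ± 54.5 and 168 ± 25.5 CPM in their controls. The overlap was 5 and 3 without dCas9 replicate 1 or 3, 10 without empty vector replicate 3, 7, 80 and 5 without overexpression replicate 1, 2 or 3, and 10 and 27 without knockout replicate 1 or 2.

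A direct test of the difference between the responses called 676 genes (5.13%), 300 with the higher response in the knockout and 376 with the lower. Interferon genes (16 of 35 lower, median −1.49) and mesenchymal genes (8 of 17 higher, median 0.93) differed as sets also with an estimated correlation (camera adjusted p = 0.024 and 0.032). Of 12 lists that passed with the preset correlation these were the only 2. The fibroblast markers were among the 12 (adjusted p = 0.046, and 0.20 with an estimated correlation). The count was 395 without dCas9 replicate 3, 414 without empty vector replicate 3, 420 without overexpression replicate 3, and 413 and 450 without knockout replicate 1 or 3. Each response is taken from its own control, so any difference between the controls enters this test. In empty vector against dCas9 cells the interferon list was higher and the mesenchymal list lower (camera adjusted p = 9.7e-07 and 0.0041). With an estimated correlation both gave 0.29. These differences push the test the same way, so it cannot tell differing responses from differing controls.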

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

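The weighing of explanations below uses tests chosen only after the results had been seen, apart from the variance left after GC correction and the splits that regroup single libraries within a comparison, whose predictions had been written before. The test of exchanged empty vector and knockout labels was among those chosen afterwards. A difference between groups brought these results here: the responses of knockout and overexpression differed for 676 genes in a direct test (limma interaction, adjusted p under 0.05). Among genes called in opposite directions, the difference of the log2 responses was −3.79 for UCHL1, −3.19 for NEURL1, −2.51 for STMN3, −2.39 for LAMA1, −1.98 for ADD2 and −1.87 for CPNE7. It was 2.95 for EDN1, 2.94 for HEPHL1 and 2.62 for FBXO32, and the interaction adjusted p of these 9 genes ran from 1e-05 (UCHL1) to 0.0011 (CPNE7). The 9 genes were selected by opposite calls in the same fit. Large differences and small p were thus built in and add no evidence. The direct test also takes in any difference between the controls.

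Labels were exchanged within the comparisons. Of the 10 splits of the knockout and empty vector libraries only 1, the real one, called as many as 650 genes, and the highest other called 0. For overexpression and dCas9 it was 1 of 10 (24 genes, highest other 0) and for the controls 1 of 10 (635 genes, highest other 1), and 0.1 is the smallest share that 10 splits allow. For the interaction 2 of 100 splits, drawn from 200, called at least 676 genes. The highest other called 3489. It placed empty vector replicates 2 and 3 with knockout replicate 2, and dCas9 replicate 1 with overexpression replicates 1 and 3. Why this split called so many genes was not tested.

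The first pattern is that the empty vector libraries stood apart from the dCas9 and knockout libraries in genes such as CBLN1, KRT4 and FBXO32. After the GC correction 1526 genes differed between the controls, more than the 635 before it. The correction also lowered the median within-group SD (log2) from 0.212 to 0.165, so the rise in count alone decides nothing about GC. Of the 635 genes 588 stayed called, so the trend that was removed did not by itself account for most of these calls. Cells with other chromosome copy numbers would shift whole chromosomes, and 15 of 23 passed the set test between the controls with an estimated correlation. Several of these shifts were small, with medians of −0.05 on chromosome 3 and −0.04 on chromosome 9, against −0.34 on chromosome 21. The set test weighs each chromosome against all other genes, so large shifts on some can move others past it. The count alone therefore does not show other copy numbers. A subline of other karyotype stays possible, but no DNA was measured. An exchange of the empty vector and knockout labels stays open, since ZC3H13 differed by only −0.08 between the controls and could not tell the groups apart. It is also open whether vector, selection or time in culture made the difference, because each control is a single line of cells.

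The second pattern is the spread of libraries of the same group along 1 main component. GC bias of the libraries could be part of it, and its test was undecided: 42.2% of the within-group variance stayed on the first component after the correction, against 57.0% before. Shared preparation would correlate same-numbered knockout, empty vector and overexpression libraries, and 9 of 9 such pairs lay above 0.1. After the GC correction these ran from 0.11 to 0.58. The same number was not the best partner for number 1 of empty vector and knockout or of overexpression and knockout. Nor was it for number 3 of empty vector and overexpression. Replicate 2 lay on the AT-rich side in each of these groups, and residuals of a group balance out. A shared deviation of replicate 2 would thus also raise the other correlations. The count alone does not single out shared preparation. For dCas9 the explanation failed, with 3 of 9 pairs above 0.1. No biological explanation of this spread was tested.

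The last pattern is that knockout and overexpression moved genes such as UCHL1, EDN1 and FBXO32 in opposite directions. A response to the level of ZC3H13 would also part knockout from dCas9 cells. The median difference of the 16 genes there was 0.04, against 1.23 from empty vector. These genes were selected by their difference from empty vector, and 14 of them also differed between the controls. That difference could offset an effect of the knockout, so the test cannot decide. A GC trend would tend to shrink the overlap on correction, which instead held 96 such genes afterwards. The correction also lowered the median within-group SD (log2) from 0.212 to 0.165, and the counts of both comparisons rose. The larger overlap therefore cannot decide whether a GC trend took part. Still called after the correction were 638 of the 650 knockout genes and 23 of the 24 overexpression genes. If overexpressing cells held part of the shift seen in empty vector cells, chromosome medians of the comparisons should mirror each other. They did, at Pearson's r = −0.76 over 23 chromosomes (permutation p = 2e-05, 100000 permutations) and −0.66 without the 2 farthest. Spearman's rho was −0.57 (permutation p = 0.0046). Genes moved in opposite directions for another reason could give such a mirror too, so it does not single out this explanation. A part played by ZC3H13 stays open, for the 16 genes as for others.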

How the results depend on the processing

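Several of the alternatives below were chosen only after the results had been seen, namely the GC correction, its combination with the block, the batch term for the library side, the fit without AT-rich libraries and median-ratio scaling. RLE size factors, DESeq2 and limma-voom were not run, since they need counts. No gene called in a main comparison changed sign when 1 library was left out, and no named gene that was called did so under any other setting. Without a filter the counts were 537 for knockout, 25 for overexpression, 520 for the controls and 605 for the interaction. They stayed near the reported values with other pseudocounts (602 to 693, and 16 to 32 for overexpression). The same held for median-ratio scaling (576 for knockout, 28 for overexpression, 650 for the controls and 647 for the interaction). The cause was not tested for the following moves unless stated. For knockout against empty vector the 650 genes became 1453 with the replicate block, 1705 with the GC correction, 2513 with both, 2153 with the library side as a batch term and 1215 without the AT-rich libraries. They became 253 with the 6 libraries alone, where fewer libraries estimate the spread, and 177 with a minimum 2-fold change, a smaller set by construction. With the block none of the 650 calls was lost, and among the knockout lists it changed only the call of the hypoxia list. For overexpression against dCas9 the 24 genes became, in the same order, 269, 128, 302, 119, 4338, 7 and 15. The replicate numbers did not pair this comparison (correlations 0.46, −0.03 and −0.07), and only number 1 was the best partner of its like. Leaving out AT-rich libraries makes the GC side coincide with the dCas9 group, so 4338 and the values of that setting below cannot be told from a GC difference. Between the controls the 635 genes became 2088, 1526, 2389, 1253 and 4475, and 153 with the minimum change, and for the interaction the 676 became 1456, 1549, 2186, 1826, 2705 and 406. Leaving out 1 library gave 223 to 740 genes for knockout (fewest without knockout replicate 1, most without knockout replicate 2), 4 to 207 for overexpression (dCas9 replicate 3 and overexpression replicate 2), 161 to 1146 for the controls (dCas9 replicate 3 and empty vector replicate 2) and 395 to 939 for the interaction (dCas9 replicate 3 and overexpression replicate 2). Replicate 2 of these groups lies on the AT-rich side, and its omission gave the highest count in all 4 cases.

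ZC3H13 on overexpression missed the threshold at 0.98 and passed at 0.98 with the block, 1 with median-ratio scaling, 1.22 with the GC correction, 1.22 with both, 1.27 with the batch term and 0.73 without AT-rich libraries, and it ranged from 0.73 to 1.18 when 1 library was left out. The 16 genes with opposite calls became 135 with the block, 96 with the GC correction, 201 with both, 84 with the batch term, 341 without AT-rich libraries and 8 with the minimum change, and 3 to 80 with 1 library left out (dCas9 replicate 3 and overexpression replicate 2). The 3 genes with calls in the same direction became 10, 5, 8, 5 and 135 under the first 5 of these settings. Of the lists, 11 for knockout became 0 with an estimated correlation, before and after the GC correction. The 5 lists for overexpression became 0 with an estimated correlation, 1 with it after the GC correction, 13 with the preset correlation after the GC correction and 14 with the block added. An estimated correlation raises the p of a list whose genes vary together, but whether this caused those losses was not tested. Among genes never called, the sign changed on overexpression for METTL3 without AT-rich libraries (−0.03), METTL14 (0.09), WTAP (0.07), MT-ND4L (−0.02) and MT-ND5 (0) with the batch term. With 1 library left out it changed in the knockout for METTL3 (−0.07 to 0.1), METTL14 (−0.47 to 0.09), VIRMA (−0.25 to 0.01) and RBM15B (−0.18 to 0.01), and on overexpression for METTL3 (−0.03 to 0.09) and CBLL1 (−0.06 to 0.13). At the median depth 1 CPM stands for 40.7 reads. With 3 libraries a group, 1.5-fold changes were found in 35.8% of simulated cases for knockout and 40.3% for overexpression. These cases were independently varying genes with a mean of at least 5 CPM, not all genes tested.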

Other observations

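Overexpressing cells were also set against the empty vector in place of dCas9, a comparison chosen only after the other results had been seen. It called 93 genes, 72 up and 21 down (limma, 1330 at an unadjusted p under 0.05). The count was 42 and 23 without empty vector replicate 1 or 3, 34 and 13 without overexpression replicate 1 or 3, 298 with the replicate block, 357 after the GC correction and 3 in a fit of these 6 libraries alone. CBLN1 stood at 36.9 ± 5.54 CPM in overexpressing cells, between 5.55 ± 0.819 CPM in empty vector and 51.8 ± 7.07 CPM in dCas9 cells, and KRT4 at 55.8 ± 15.5 CPM, between 114 ± 7.49 and 26.4 ± 8.58 CPM. ALPP stood apart in overexpressing cells alone, at 89.5 ± 21.4 CPM against 11.1 to 13.3 CPM in the other groups.

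The deposited results of the authors were read as values only. Their adjusted p-value was under 0.05 for 49153 of 110474 transcripts between knockout and empty vector (44.5%), of which 34288 had a mean below 1 CPM, and for 1717 (1.6%) between overexpression and dCas9. The log2 ratio column held a fixed error value for 17439 transcripts in the first comparison and 12263 in the second, and these cells carry no ratio. For ZC3H13 the deposited log2 ratio of transcript ENST00000679008.1 was 1.31 on overexpression (authors' adjusted p-value 3.96e-07) and −0.29 in the knockout (0.0817). For the next most abundant, ENST00000242848.8, it was 0.73 (0.205) and −0.35 (0.0417). The share of mitochondrially encoded genes was 2.28 to 3.77% of CPM over the 12 libraries, and that of the 10 most abundant genes 5.8 to 7.4%.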
